A study of Mus musculus with 12 samples.

How the data were processed

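Fat tissue of 10 male C57BL/6 mice aged 42 to 49 days was, per the labels, pooled by depot and digested with collagenase at 1 mg/ml for 45 min. The floating adipocytes were separated from the stromo-vascular cells, which went through lysis of red cells and were plated, with RNA taken after 16 h of culture. For each array 15 µg of RNA was labelled. The 12 arrays, 3 per group, are Affymetrix expression arrays of 12488 probe sets. The deposited values are an intensity on a linear scale, 1 per probe set and array, which the authors computed with MAS5 as named in their processing notes; its version and its detection calls are not given in the sources used here. The 2% trimmed means of the arrays lay within a ratio of 1.00017 of each other, so each array had been scaled to a common level, and the values were taken as deposited, as planned for trimmed means within a factor of 1.5. No 2 arrays were identical (0 pairs). Whether the 3 replicates of a group are separate pools of tissue is not stated, so p-values measure the spread between these samples only.

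The 66 control probe sets were left out, which left 12422. Of these 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 had none here, and no gene was named from a probe set with several. The annotation can be old: 10817 probe sets were matched to current gene records by Entrez number and 0 symbols needed an update. In all 8251 genes were named. No reference genome came with the series, so no positions are given. The test used log2 of the signal plus a pseudocount of 40.09, the 10th percentile of all values, and a fold is given on that scale, which understates the change of dim genes. Probe sets in the lowest 30% of mean log2 signal were left out, and 8695 were tested. For a gene with several probe sets the one with the highest mean stood for the gene, which gave 6436 genes for the list tests, and probe sets of a named gene that pointed the other way are mentioned.

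A model with 4 group means was fitted to all 12 arrays with limma 3.58.1 (lmFit, contrasts and eBayes with an intensity trend) in R 4.3.3, so that the groups shared 1 estimate of the spread with 8 residual degrees of freedom and a median of 6.17 prior degrees of freedom. Adjusted p-values are those of limma after Benjamini-Hochberg adjustment over the probe sets tested in a contrast, and a probe set was called when its adjusted p was under 0.05. The contrasts were subcutaneous minus intraabdominal adipocytes, subcutaneous minus intraabdominal stromo-vascular cells, adipocytes minus stromo-vascular cells in each depot, and the interaction, the depot difference in adipocytes minus that in stromo-vascular cells. Overlap of calls was tested with Fisher's exact test. The median standard error of a log2 difference was 0.241, and 0.341 for the interaction. Simulated data with 200 of 8695 probe sets changed went through the same steps. They recovered 51% to 63% of 2-fold and 89% to 96% of 4-fold changes in the 2-group contrasts, and 29% and 79% in the interaction. False calls made up 4.08% to 7.02% of calls. Residual SDs (log2) were 0.42 to 0.49 in adipocyte and 0.32 to 0.35 in stromo-vascular groups, so these shares may differ by contrast.

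The 26 gene lists were fixed before the data were examined, as were the contrasts, the test, the filter, the pseudocount rule and the rule for naming genes. The lists held markers of adipocytes, brown fat, preadipocytes and fibroblasts, macrophages, T and B lymphocytes, endothelium, smooth muscle and pericytes, mesothelium, skeletal muscle, epididymis and testis, keratinocytes and skin, and erythroid cells. They also held genes of fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation and extracellular matrix. The rest were Hox genes, other patterning regulators, Wnt, BMP and TGF beta signalling, cell cycle, immediate early and dissociation stress, cytokines and chemokines, glycolysis and hypoxia, the insulin, IGF and steroid axis, and complement and coagulation. Each list with at least 5 measured genes was tested with camera of limma at a preset correlation of 0.01, adjusted over the 26 lists of a contrast. Camera with an estimated correlation was an alternative, as was fry, which tests whether a list's genes move on balance in 1 direction. Genes were named by rule. It took the 8 largest log2 differences in each direction (5 for the interaction) among called genes whose groups did not overlap and whose higher group reached the median of all values, 496. It also took up to 4 members of each list with the smallest p and every Hox and patterning gene called in a depot contrast. The text takes part of the genes so named, and gives for the interaction only genes also named in another contrast or among its own leading ones.

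The quality measures were the median signal, the 3' to 5' ratios of the actin and GAPDH control probe sets, the spiked bacterial controls and the share of signal in the 10 brightest probe sets, compared with exact permutation tests. The GAPDH ratio was 2.06 ± 0.16 in subcutaneous adipocytes, 1.73 ± 0.18 in intraabdominal adipocytes, 1.17 ± 0.05 in subcutaneous and 1.04 ± 0.04 in intraabdominal stromo-vascular cells (SD, n = 3). The 10 brightest probe sets took 6.55%, 6.49%, 3.46% and 3.27% of the signal in the same order. The spiked controls (geometric mean) read 9277 ± 2645, 15365 ± 7238, 6249 ± 515 and 5868 ± 941 in that order, with an exact permutation p of 0.0022 between the fractions and of 0.2 and 0.6 between the depots in adipocytes and stromo-vascular cells. Alternatives were a pseudocount of 1 or of the 30th percentile (170), no filter or a filter of 60%, quantile normalization, median centring, no intensity trend and array quality weights. Further ones were a fit of only the 6 arrays compared, a replicate block, 1 probe set per gene, a 2-fold minimum, the mean of all probe sets of a gene, and leaving out each array in turn. The actin 3' to 5' ratio as a covariate was added after seeing the data, and later the GAPDH ratio, for counts of calls and tests of explanations only. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0.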

Results

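The study compared fat tissue of 2 depots, each separated into 2 cell fractions, in young male C57BL/6 mice, an inbred laboratory strain. Messenger RNA was measured on 12 arrays in 4 groups of 3: adipocytes of subcutaneous (flank) fat, adipocytes of intraabdominal (epididymal) fat, and stromo-vascular cells of each of the same depots. The stromo-vascular fraction is the mixture of fat cell precursors, fibroblasts, vessel cells and immune cells left once the fat cells float off digested tissue. It was plated and cultured for 16 h before RNA was taken, so fraction and culture went together. The median signal of an array averaged 523 ± 42.0 in subcutaneous adipocytes, 444 ± 34.3 in intraabdominal adipocytes, 519 ± 13.1 in subcutaneous stromo-vascular cells and 497 ± 13.2 in intraabdominal stromo-vascular cells (SD, n = 3 each). Arrays of 1 group correlated with Pearson's r between 0.924 and 0.976 across probe sets, which are not independent replicates. The ratio of signal at the 3' end to signal at the 5' end of the actin transcript, which rises as RNA breaks down, was 2.85 ± 0.43 in subcutaneous adipocytes, 2.04 ± 0.29 in intraabdominal adipocytes, 1.22 ± 0.02 in subcutaneous and 1.17 ± 0.05 in intraabdominal stromo-vascular cells. Over all 6 adipocyte and 6 stromo-vascular arrays this ratio differed with a two-sided exact permutation p of 0.0022, the smallest that 924 splits allow. Between the adipocytes of the 2 depots the exact permutation p was 0.1, the smallest possible with 3 arrays against 3. The number of arrays limited the precision of every value. Signals below are means ± SD over 3 arrays, and folds were taken on the scale of the signal plus the pseudocount. In each gene given below as differing between 2 groups all 3 arrays of the higher group lay above all 3 of the other.

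The first comparison asked which genes distinguish fat cells of the subcutaneous depot from fat cells of the intraabdominal depot. Subcutaneous adipocytes carried far more RNA of genes known from brown and thermogenic fat. Cidea, a lipid droplet protein abundant in brown fat, read 17639 ± 2895 against 782 ± 266 in intraabdominal adipocytes (22.1-fold, adjusted p = 6.25e-06). Ucp1, the uncoupling protein that lets brown fat mitochondria produce heat, read 1326 ± 171 against 143 ± 52.6 (7.65-fold, adjusted p = 0.000301). Intraabdominal adipocytes carried more Agt, the precursor of angiotensin, at 16339 ± 2239 against 2185 ± 210 (7.34-fold, adjusted p = 8.94e-08). Of the 8695 probe sets tested, 707 (8.13%) differed, 345 higher and 362 lower in subcutaneous adipocytes.

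Of the brown fat and thermogenic markers 5 of 6 tested members (11 on the array) were higher in subcutaneous adipocytes (5 also when adjusted over the list alone). Their median log2 difference was 2.84, with adjusted p = 2.1e-07 for the list and adjusted p = 0.145 with an estimated correlation. Besides Cidea and Ucp1 these included Cox8b (7.80-fold) and Cox7a1 (6.69-fold), subunits of the terminal respiratory enzyme typical of brown fat and muscle. The skeletal muscle markers had a median of 0.27 with 1 of 12 members lower and adjusted p = 0.465. That member was the muscle actin Acta1, 2.87-fold lower in subcutaneous adipocytes. The subcutaneous adipocytes were also the group with the highest actin 3' to 5' ratio. Among 16 genes of fatty acid oxidation 3 were higher and 1 lower (8 higher and 1 lower when adjusted over the list alone; median 0.41, adjusted p = 0.00891, adjusted p = 0.245 with an estimated correlation). Hadhb, part of the mitochondrial trifunctional protein, was 1.70-fold higher, whereas Cpt1a, which moves long-chain fatty acids into mitochondria, was 2.02-fold lower. Among 31 genes of oxidative phosphorylation 2 were higher (2 when adjusted over the list alone; median 0.23, adjusted p = 0.00849, adjusted p = 0.661 with an estimated correlation). Both of these list calls were lost without subcutaneous adipocyte array 3 (adjusted p = 0.136 and 0.177) and with each array centred on its median (0.0728 and 0.121). Over all alternatives the adjusted p ran from 5.19e-05 to 0.245 for fatty acid oxidation, from 3.47e-07 to 0.661 for oxidative phosphorylation and from 1.99e-09 to 0.145 for the brown fat markers. In fatty acid and triglyceride synthesis 2 of 12 genes were higher (5 when adjusted over the list alone; adjusted p = 0.0902 for the list), among them the fatty acid elongase Elovl6 at 7803 ± 1392 against 1681 ± 382 (4.58-fold, adjusted p = 0.00035).

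The largest differences toward subcutaneous adipocytes were those of Mup3, at 18992 ± 3850 against 398 ± 74.1 (43.3-fold, adjusted p = 1.79e-07), and Mup5 (26.5-fold). These encode major urinary proteins, small carriers of odorants made in liver and glands, and the family's members are so alike in sequence that a probe set may not tell them apart. Scx, a regulator of tendon cells, was 7.03-fold higher. Genes with large differences toward intraabdominal adipocytes, besides Agt and the nuclear receptor Nr2f1, were Cyp1b1, an enzyme that oxidises steroids and foreign compounds (1289 ± 374 against 118 ± 57.1, 8.55-fold, adjusted p = 8.53e-07), Rhbdl3 (5.27-fold), the growth factor Tgfb1 (4.80-fold), Plaur, the urokinase receptor (4.34-fold), Reep6 (3.86-fold) and the glucose transporter Slc2a1 (3.83-fold). Of 20 adipocyte markers 1 was higher and 2 lower, the same counts when adjusted over the list alone (adjusted p = 0.318 for the list, whose median was -0.04 and whose test pointed down). The higher member was Cidea. The lower members were Agt and Lep, the satiety hormone leptin, which read 25104 ± 8372 against 53545 ± 13763 (2.15-fold, adjusted p = 0.0227), and another Lep probe set was called in the same direction.

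Matrix genes moved both ways. Of 32 tested 5 were higher and 3 lower in subcutaneous adipocytes (7 and 3 when adjusted over the list alone; list adjusted p = 0.295). Col1a1 and Col1a2, the chains of type I collagen, were 4.65-fold (20488 ± 2199 against 4377 ± 549) and 3.04-fold higher, and the matrix protein Postn was 1.91-fold higher. Col6a1 was 1.68-fold and Ogn, a small proteoglycan, 3.46-fold lower. Of 19 preadipocyte and fibroblast markers 3 were higher and 1 lower (8 and 2 when adjusted over the list alone; list adjusted p = 0.194). Of 25 cytokines and chemokines 2 were higher and 3 lower (2 and 9 when adjusted over the list alone; median -0.28, list adjusted p = 0.0902). The chemokine Ccl8 was 3.42-fold higher and the acute-phase proteins Saa3 and Lcn2 were 2.76-fold and 3.21-fold lower, though another Lcn2 probe set, not called, pointed the other way. The Wnt antagonist Sfrp2 was 5.04-fold higher, and Thbd, the endothelial thrombin receptor, 2.54-fold lower. Among 26 immediate early and dissociation stress genes 1 was higher and 4 lower (2 and 5 when adjusted over the list alone; list adjusted p = 0.673, median 0.10 and test direction down). They included Socs3, a brake on cytokine signalling, 4.86-fold higher, and the transcription factors Nr4a1 and Fosl1 3.09-fold and 2.94-fold lower. The cell cycle list had 4 of 25 genes higher (4 when adjusted over the list alone; adjusted p = 0.0902).

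The median difference of all probe sets was 0.07, and -0.15 once each array was centred on its median. In that setting 172 of 958 called probe sets were higher in subcutaneous adipocytes, 17.9% against 48.8% as deposited. The count also moved with single arrays, to 365 without intraabdominal adipocyte array 2 and 372 without array 1. The call of Slc2a1 was lost without array 1 (adjusted p = 0.0537) or 2 (0.0516) of that group. The call of Lep was lost without subcutaneous adipocyte array 2 (adjusted p = 0.0633) or 3 (0.0662) or intraabdominal adipocyte array 1 (0.0976) or 2 (0.099). Their log2 differences were then -1.54 to -1.64 for Slc2a1 (-1.94 with all arrays) and -0.91 to -1.05 for Lep (-1.11). With the actin ratio as a covariate, an alternative chosen after seeing the data, 97 probe sets were called. The adjusted p rose to 0.0692 for Ucp1, 0.176 for Scx, 0.137 for Tgfb1, 0.0866 for Plaur, 0.0692 for Col6a1, 0.0981 for Postn, 0.176 for Lcn2 and 0.0692 for Saa3. These were the highest values of these genes over all alternatives, and the lowest lay between 9.07e-06 (Saa3) and 0.000747 (Col6a1). The log2 differences (± SE) changed by less than the SE of the covariate fit. With the covariate they were 2.48 ± 0.596 (Ucp1; 2.93 ± 0.371 without it), 2.52 ± 0.814 (Scx; 2.81 ± 0.479), -2.00 ± 0.591 (Tgfb1; -2.26 ± 0.353), -2.48 ± 0.631 (Plaur; -2.12 ± 0.38), -0.763 ± 0.182 (Col6a1; -0.749 ± 0.112), 0.90 ± 0.238 (Postn; 0.93 ± 0.143), -1.42 ± 0.457 (Lcn2; -1.68 ± 0.275) and -1.70 ± 0.408 (Saa3; -1.46 ± 0.244). For Slc2a1 the range over alternatives was 3.89e-06 to 0.412 and for Lep 0.00765 to 0.233.

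**Figure D1:**
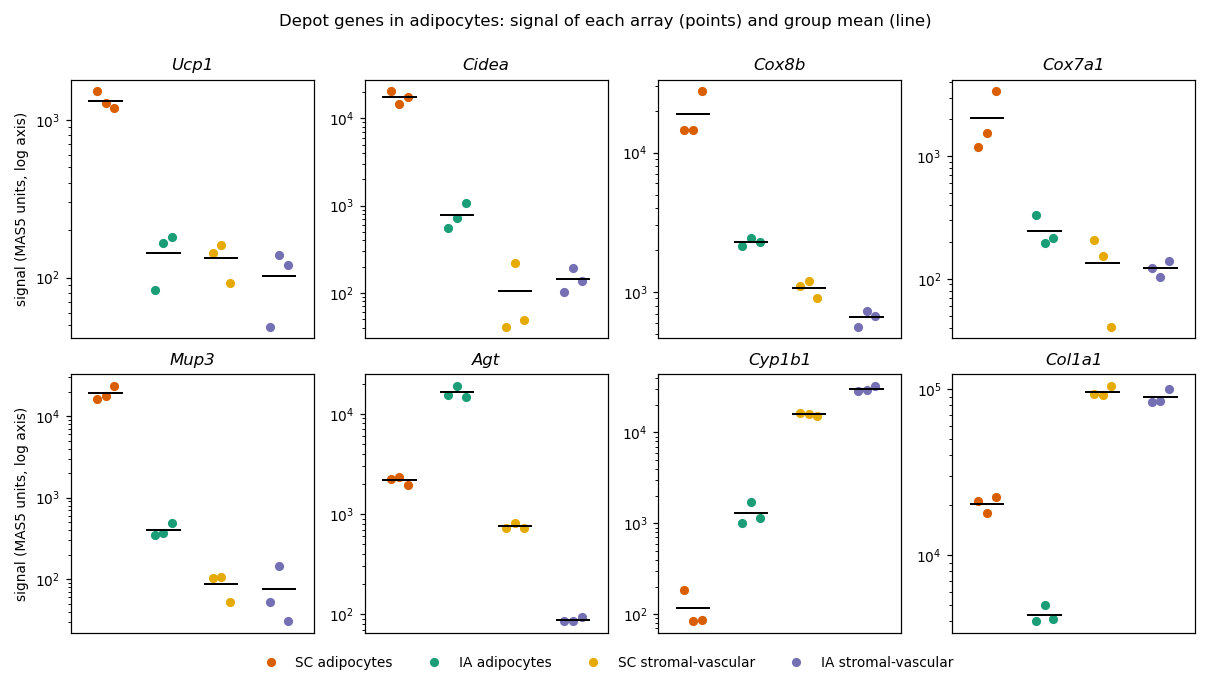
Signal on a log axis of 8 genes on each of the 3 arrays of subcutaneous and of intraabdominal adipocytes; each point is 1 array and each line a group mean. Mup3 averaged 18992 against 398, Cidea 17639 against 782 and Ucp1 1326 against 143, while Agt averaged 2185 against 16339 and Cyp1b1 118 against 1289.

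The second comparison asked which genes distinguish plated stromo-vascular cells of the 2 depots. Intraabdominal stromo-vascular cells carried much more RNA of smooth muscle and mesothelial genes. Cnn1, calponin of contractile smooth muscle, read 9631 ± 403 against 110 ± 108 in subcutaneous cells (75.6-fold, adjusted p = 1.38e-07). Myh11, smooth muscle myosin, read 7898 ± 1595 against 98.8 ± 63.5 (61.1-fold, adjusted p = 3.83e-06). Subcutaneous stromo-vascular cells carried more of several secreted proteins, led by Ccl8, a chemokine that attracts monocytes, at 33115 ± 590 against 624 ± 93.7 (50.2-fold, adjusted p = 1.97e-08). Of 8695 probe sets 1125 (12.94%) differed, 564 higher and 561 lower in subcutaneous cells.

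Of 12 smooth muscle and pericyte markers 9 were lower in subcutaneous than in intraabdominal stromo-vascular cells and none higher (10 lower when adjusted over the list alone). Their median log2 difference was -1.69 (adjusted p = 6.5e-13, adjusted p = 0.0265 with an estimated correlation). They included the gamma actin Actg2, at 18743 ± 1976 against 1785 ± 216 (10.3-fold). Of 7 mesothelial markers 5 were lower in subcutaneous cells (6 when adjusted over the list alone; median -2.09, adjusted p = 1.65e-05, adjusted p = 0.0497 with an estimated correlation). Among them were Wt1, a transcription factor of the body cavity lining (5.48-fold), and the surface protein Upk3b (6.64-fold). Macrophage markers were also mostly higher in intraabdominal cells. Of these 9 of 17 were lower in subcutaneous cells and 1 higher (10 and 1 when adjusted over the list alone; median -1.31, adjusted p = 9.81e-07, adjusted p = 0.282 with an estimated correlation). The complement chains C1qa and C1qb, made by tissue macrophages, were 6.97-fold and 8.06-fold and the macrophage perforin Mpeg1 3.36-fold higher there. Another C1qb probe set, not called, pointed the other way. Endothelial markers went in the other direction. Of these 7 of 13 were higher in subcutaneous cells (7 higher and 2 lower when adjusted over the list alone; median 0.95, adjusted p = 0.0178, adjusted p = 0.389 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, read 379 ± 78.8 against 66.8 ± 31.9 (3.99-fold), and the receptor partner Ramp2 was 3.0-fold higher.

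Of 25 cytokines and chemokines 10 were higher and 1 lower in subcutaneous stromo-vascular cells (13 and 2 when adjusted over the list alone; median 0.71, adjusted p = 6.56e-05, adjusted p = 0.282 with an estimated correlation). Besides Ccl8 these were led by Cxcl14 (23501 ± 1054 against 2030 ± 364, 11.5-fold) and Ccl11, an attractant of eosinophils (7.11-fold). Other genes with large differences toward subcutaneous cells were Serpinb2 (13.3-fold) and Serpina3n (34432 ± 4805 against 2925 ± 724, 11.8-fold), both protease inhibitors, Myl1, a muscle myosin light chain (12.4-fold), Itm2a (10.2-fold), Sfrp2 (9.70-fold), Dpt, a dermal matrix protein (9.13-fold), and Ace, the angiotensin-converting enzyme (8.10-fold). Toward intraabdominal cells they were Aldh1a3, which makes retinoic acid (20.5-fold), Igfbp2 (17.7-fold) and Igfbp3 (36337 ± 5421 against 3560 ± 830, 10.2-fold), which bind insulin-like growth factors, Cck, the gut hormone cholecystokinin (14.1-fold), the vesicle protein Vamp5 (12.9-fold) and Timp3, an inhibitor of matrix proteases (10.2-fold). Mmp3, a matrix protease, was 4.77-fold higher in subcutaneous cells at 68072 ± 3875, and Thbd 3.12-fold higher in intraabdominal cells.

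Of 32 matrix genes 8 were higher and 5 lower in subcutaneous stromo-vascular cells (9 and 6 when adjusted over the list alone; list adjusted p = 0.595). Col6a1, lower in subcutaneous adipocytes, was 2.30-fold higher. Of 19 preadipocyte and fibroblast markers 5 were higher and 3 lower (6 and 3 when adjusted over the list alone; list adjusted p = 0.595). Of 20 adipocyte markers 5 were higher and 1 lower (the same when adjusted over the list alone; list adjusted p = 0.149). Agt was 6.16-fold higher in subcutaneous cells (754 ± 54.8 against 88.7 ± 5.32), opposite to adipocytes. Rbp4, the plasma carrier of retinol, was 3.98-fold higher and the fatty acid receptor Cd36 3.21-fold lower. The fatty acid desaturase Scd1 was 2.43-fold higher, with an uncalled probe set of the other sign, and Cpt1a 2.60-fold lower. Brown fat markers gave no call among 6 (none when adjusted over the list alone; list adjusted p = 0.863). Cidea read 104 ± 102 against 144 ± 45.5 (adjusted p = 0.434), and was called lower without subcutaneous array 2 (log2 difference -1.08, adjusted p = 0.0375). In the list of insulin, IGF and steroid genes 6 of 18 were higher and 4 lower (6 and 5 when adjusted over the list alone; list adjusted p = 0.841). The median of that list was 0.08 against a mean of -0.15 and a test direction of down. Of 32 Wnt, BMP and TGF beta genes 4 were higher and 9 lower (5 and 10 when adjusted over the list alone; list adjusted p = 0.171). Of 16 genes of fatty acid oxidation 1 was higher and 5 lower (3 and 8 when adjusted over the list alone; list adjusted p = 0.0535).

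Cell cycle genes were lower in subcutaneous cells in 4 of 25 cases (5 when adjusted over the list alone; median -0.30, adjusted p = 0.0173, adjusted p = 0.111 with an estimated correlation), with Rrm1, a subunit of ribonucleotide reductase, 3.31-fold lower. That list's call was lost without subcutaneous stromo-vascular array 3 (adjusted p = 0.0528), and over all alternatives its adjusted p ran from 0.00167 to 0.111. The other ranges were 2.08e-08 to 0.282 for macrophage markers, 2.52e-05 to 0.282 for cytokines and chemokines and 0.00659 to 0.389 for endothelial markers. Array quality weights gave 1952 calls and the 6 stromo-vascular arrays alone 1690.

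**Figure D2:**
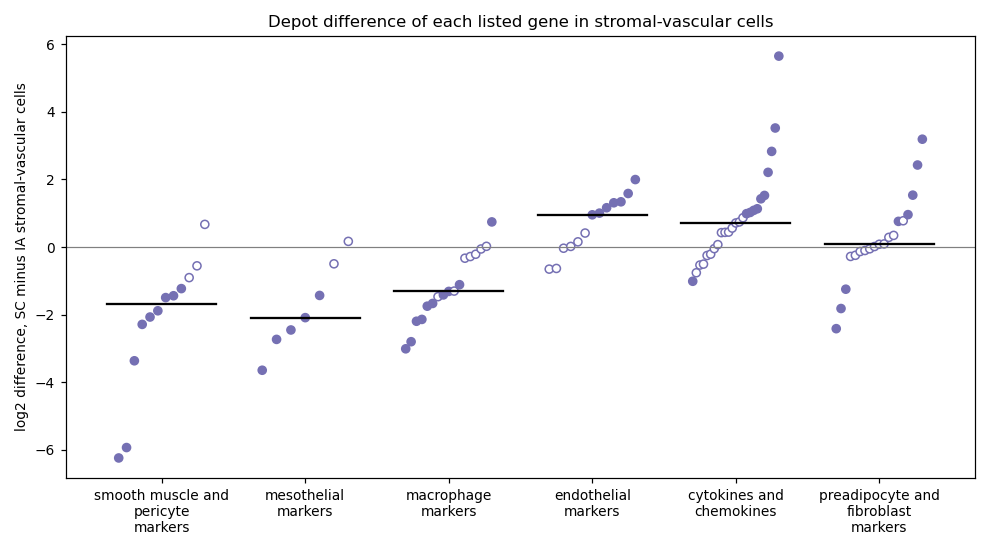
Log2 difference between subcutaneous and intraabdominal stromo-vascular cells (3 arrays each) for the genes of 6 marker lists; each point is 1 gene, filled where called, and the line is the list's median. The medians were -1.69 for smooth muscle and pericyte, -2.09 for mesothelial, -1.31 for macrophage and 0.95 for endothelial markers.

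Several genes that set position in the embryo differed between the depots in both fractions, though neither list of such genes was called in either depot contrast. The Hox genes, which mark position along the body axis, and the other patterning regulators are known from published work on these fat depots, and these arrays may be part of that work, so their counts here are not independent evidence. Shox2, a homeobox gene of limb development, was higher in subcutaneous cells of both fractions: 2457 ± 104 against 282 ± 23.6 in adipocytes (7.76-fold, adjusted p = 3.78e-07) and 3622 ± 362 against 397 ± 104 in stromo-vascular cells (8.51-fold, adjusted p = 8.11e-08). En1, a homeobox gene of the ventral limb and hindbrain, was also higher in both, 5.25-fold (423 ± 101 against 53.1 ± 45.6, adjusted p = 0.000371) and 2.06-fold (adjusted p = 0.0394). Tcf21, a mesoderm regulator, was lower in subcutaneous cells, 2.52-fold in adipocytes (106 ± 60.4 against 320 ± 108, adjusted p = 0.0236) and 38.9-fold in stromo-vascular cells (50.2 ± 0.488 against 3470 ± 136, adjusted p = 8.11e-08).

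Of 21 Hox genes 1 was higher and 2 lower in subcutaneous adipocytes (8 and 2 when adjusted over the list alone; median 0.42, list adjusted p = 0.295). In turn 3 were lower and none higher in subcutaneous stromo-vascular cells (3 when adjusted over the list alone; median -0.15, list adjusted p = 0.061). Hoxa5 was lower in subcutaneous cells of both fractions, 1.90-fold in adipocytes (838 ± 236 against 1605 ± 311, adjusted p = 0.0218) and 6.04-fold in stromo-vascular cells (243 ± 39.6 against 1657 ± 45.4, adjusted p = 2.05e-06). Hoxc8 was lower in both as well, 1.56-fold (adjusted p = 0.033) and 2.86-fold (adjusted p = 2.42e-05). Hoxa7 was 4.58-fold lower in subcutaneous stromo-vascular cells (adjusted p = 0.000203) and read 987 ± 327 against 1612 ± 508 in adipocytes (adjusted p = 0.196). Hoxc9 was 1.73-fold higher in subcutaneous adipocytes (adjusted p = 0.0222) and read 565 ± 76.4 against 748 ± 36.5 in stromo-vascular cells (adjusted p = 0.232).

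Of 39 other patterning regulators 3 were higher and 3 lower in subcutaneous adipocytes (4 and 3 when adjusted over the list alone; list adjusted p = 0.194). In subcutaneous stromo-vascular cells 4 were higher and 9 lower (4 and 9 when adjusted over the list alone; list adjusted p = 0.251, median 0.07 against a mean of -0.26 and a test direction of down). Nr2f1, a nuclear receptor, was lower in subcutaneous cells of both fractions, 4.93-fold and 4.46-fold, and so was the cell surface proteoglycan Gpc4, 1.49-fold and 3.34-fold. Gata2, a regulator of blood and fat precursor cells, was 1.64-fold higher in subcutaneous adipocytes and 2.39-fold lower in subcutaneous stromo-vascular cells. Called in stromo-vascular cells and not in adipocytes, Irx3 (1987 ± 83.2 against 415 ± 2.72, 4.45-fold) and Twist2 (2.30-fold) were higher and Bnc1, a regulator of epithelial cells (12.5-fold), Wt1, Nr2f2 (3.23-fold), Gata6 (2.14-fold) and Eya2 (2.03-fold) lower. Their adjusted p in adipocytes was 0.963 for Irx3, 0.967 for Twist2, 0.149 for Bnc1, 0.855 for Wt1, 0.375 for Nr2f2, 0.743 for Gata6 and 0.9 for Eya2. Bnc1 was called higher in subcutaneous adipocytes without intraabdominal adipocyte array 3 (log2 difference 1.45, adjusted p = 0.0492). The interaction test was passed by Irx3 (log2 difference -2.17), Bnc1 (4.71), Wt1 (2.58), Nr2f2 (2.17) and Gata6 (1.21). With the actin ratio as a covariate, chosen after seeing the data, that test's adjusted p was 0.0828 for Wt1, 0.142 for Nr2f2 and 0.103 for Gata6, the highest over their alternatives, at log2 differences (± SE) of 2.10 ± 0.624 (0.501 without the covariate), 1.41 ± 0.492 (0.448) and 1.06 ± 0.336 (0.265). Another Gata6 probe set, not called, had the opposite sign in stromo-vascular cells.

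Several of these calls were lost when 1 array was left out, while their log2 differences kept their sign. In adipocytes the call of Hoxa5 was lost without subcutaneous array 2 (adjusted p = 0.0545) or 3 (0.0555) or intraabdominal array 1 (0.0726) or 3 (0.0576). That of Hoxc8 was lost without subcutaneous array 1 (0.0738) or 2 (0.107), intraabdominal array 1 (0.0928) or 3 (0.0767) or subcutaneous stromo-vascular array 2 (0.0501). The call of Hoxc9 was lost without subcutaneous array 1 (0.0598) or 2 (0.0525) or intraabdominal array 1 (0.0668) or 2 (0.0926), and that of Tcf21 without subcutaneous array 2 (0.0547) or 3 (0.054) or intraabdominal array 2 (0.109). Gpc4 lost its call without intraabdominal array 2 (0.0705), and Gata2 without any of the 12 arrays except intraabdominal adipocyte array 3 (up to 0.155, without intraabdominal array 1). In stromo-vascular cells the call of En1 was lost without any of the 6 arrays compared (up to 0.157, without subcutaneous array 3). Where the call was lost the log2 difference was -0.75 to -0.91 for Hoxa5 (-0.92 with all arrays), -0.49 to -0.64 for Hoxc8 (-0.64), 0.69 to 0.79 for Hoxc9 (0.79), -1.08 to -1.27 for Tcf21 (-1.33), -0.57 for Gpc4 (-0.58), 0.50 to 0.79 for Gata2 (0.71) and 0.95 to 1.12 for En1 (1.04). Over all alternatives the adjusted p in adipocytes ran from 0.00261 to 0.145 for Hoxa5, 0.00841 to 0.695 for Hoxc8, 0.015 to 0.385 for Hoxc9, 0.0045 to 0.185 for Tcf21, 0.00174 to 0.115 for Gpc4, 0.0195 to 0.572 for Gata2, 2.96e-05 to 0.0645 for En1 and 0.000179 to 0.0567 for Nr2f1. The highest came with only the 6 arrays compared for Tcf21 and Gpc4. For the others it came with the actin covariate, where the log2 difference (± SE) was -1.20 ± 0.362 for Hoxa5, -0.32 ± 0.258 for Hoxc8 (-0.64 ± 0.170 without it), 0.67 ± 0.313 for Hoxc9, 0.50 ± 0.317 for Gata2 (0.71 ± 0.197), 2.21 ± 0.519 for En1 and -2.93 ± 0.668 for Nr2f1.

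**Figure D3:**
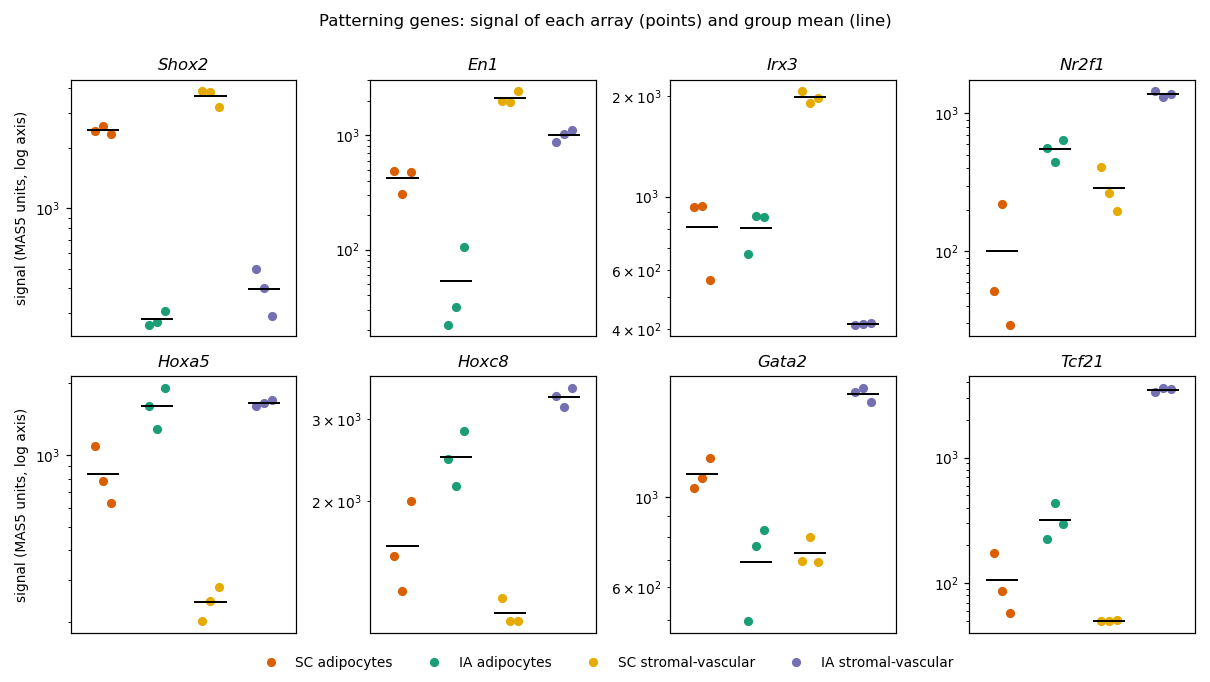
Signal on a log axis of 8 patterning genes on each of the 12 arrays, in 4 groups of 3; each point is 1 array and each line a group mean. Shox2 lay higher in subcutaneous than in intraabdominal cells of both fractions (2457 against 282 in adipocytes, 3622 against 397 in stromo-vascular cells), whereas Hoxa5 lay lower (838 against 1605 and 243 against 1657).

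Depot differences recurred in both fractions more often than independent lists would overlap. Shox2, En1, Sfrp2 and Ccl8 were among the genes higher in subcutaneous cells of both fractions, and Hoxa5, Hoxc8, Nr2f1, Tcf21, Gpc4, Thbd and Cpt1a among those lower in both. In all 66 probe sets were called higher in both (22.38 expected of independent lists, Fisher's exact p = 4.55e-16) and 96 lower in both (23.36 expected, p = 2.36e-35), over probe sets that are not independent. Another 66 were called in opposite directions (45.74 expected), including Agt, Gata2 and Col6a1. Across the 8695 probe sets the 2 depot differences correlated with r = 0.148. The count of 162 shared calls became 96 without intraabdominal adipocyte array 1, 102 without array 2 of that group and 105 without subcutaneous stromo-vascular array 2. Other settings gave 106 without the intensity trend, 91 with only the 6 arrays compared and 39 with the actin covariate.

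The next pair of comparisons asked how fat cells differ from plated stromo-vascular cells within each depot. In subcutaneous fat the adipocytes were marked by the products of mature fat cells. Car3, the carbonic anhydrase of fat and muscle, read 230098 ± 31197 against 48.0 ± 14.0 (2619-fold, adjusted p = 3.71e-15). The hormones Retn (resistin, 858-fold) and Adipoq (adiponectin, 140415 ± 20112 against 245 ± 46.3, 494-fold) followed the same direction. The stromo-vascular cells carried far more Ccn2, a matrix-associated growth regulator, at 61575 ± 4016 against 87.4 ± 89.2 (565-fold, adjusted p = 3.5e-10). Of 8695 probe sets 4594 (52.83%) differed in subcutaneous fat, 2041 higher and 2553 lower in adipocytes.

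In intraabdominal fat the same markers led. Car3 read 245981 ± 30842 in adipocytes against 50.6 ± 21.0 (2744-fold, adjusted p = 2.66e-15). Retn was 1383-fold, Plin4, a lipid droplet coat protein, 692-fold and Adipoq 685-fold higher, and Ccn2 was 433-fold lower (adjusted p = 4.74e-10). Of 8695 probe sets 4462 (51.32%) differed, 1944 higher and 2518 lower in adipocytes. The depots shared 3433 of these calls in direction, 1494 higher and 1939 lower, with 59 in opposite directions. The 2 fraction differences correlated with r = 0.854 across probe sets.

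All 20 adipocyte markers were higher in adipocytes of both depots (20 when adjusted over the list alone). The median was 5.79 in subcutaneous fat (adjusted p = 4.7e-18, adjusted p = 0.0015 with an estimated correlation) and 5.12 in intraabdominal fat (adjusted p = 7.63e-19, adjusted p = 0.00128 with an estimated correlation). The esterase Ces1d (714-fold and 608-fold), the imprinted gene Nnat (476-fold and 473-fold), Thrsp, a regulator of lipid synthesis (423-fold and 425-fold), Cidec, a lipid droplet protein (421-fold and 652-fold), and in subcutaneous fat Pck1, an enzyme of glycerol formation (215-fold), were among the leading genes. Fatty acid and triglyceride synthesis was higher in 10 of 12 genes in subcutaneous fat (adjusted p = 4.35e-09, adjusted p = 0.0359 with an estimated correlation). It was higher in 11 of 12 in intraabdominal fat (adjusted p = 6.5e-10, adjusted p = 0.0282 with an estimated correlation), the same counts as when adjusted over the list alone. Fasn, fatty acid synthase, was 57.6-fold and 51.3-fold and Scd1 15.8-fold and 29.2-fold higher. Fatty acid oxidation was higher in 14 of 16 genes in each depot, with 1 lower in intraabdominal fat (adjusted p = 1.58e-09 and 1.83e-07, adjusted p = 0.00586 and 0.0142 with an estimated correlation; the same counts when adjusted over the list alone). The dehydrogenase Acadm was 19.3-fold and 13.2-fold higher. Oxidative phosphorylation was higher in 29 of 31 genes in each depot (29 when adjusted over the list alone; adjusted p = 4.53e-15 and 4.62e-13, adjusted p = 0.0359 and 0.0436 with an estimated correlation). Cytochrome c1, Cyc1, was 5.03-fold and 4.12-fold higher. Brown fat markers were higher in 5 of 6 genes in subcutaneous fat (5 when adjusted over the list alone; adjusted p = 0.000412, adjusted p = 0.108 with an estimated correlation), Cidea by 141-fold. They were higher in 3 of 6 in intraabdominal fat (3 when adjusted over the list alone; list adjusted p = 0.0658).

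Matrix genes were lower in adipocytes. This held for 23 of 32 in subcutaneous fat with 6 higher (24 and 6 when adjusted over the list alone; adjusted p = 6.3e-07, adjusted p = 0.0537 with an estimated correlation). It held for 22 of 32 in intraabdominal fat with 6 higher (22 and 6 when adjusted over the list alone; adjusted p = 6.41e-06, adjusted p = 0.0605 with an estimated correlation). Timp1, a protease inhibitor, was 28.4-fold lower in each depot and Lox, which crosslinks collagen, 46.1-fold and 55.7-fold lower. Preadipocyte and fibroblast markers were lower in 13 of 19 genes in subcutaneous fat with 3 higher (14 and 3 when adjusted over the list alone; adjusted p = 0.00113, adjusted p = 0.0832 with an estimated correlation). In intraabdominal fat 14 were lower and 4 higher (14 and 4 when adjusted over the list alone; adjusted p = 0.00278, adjusted p = 0.0909 with an estimated correlation). Wnt, BMP and TGF beta genes were lower in 23 of 32 in each depot, with 3 higher in subcutaneous and 1 in intraabdominal fat (23 lower in each and 3 and 2 higher when adjusted over the list alone). The list's adjusted p was 0.000107 and 1.49e-05, with adjusted p = 0.0359 and 0.0259 with an estimated correlation. The activin subunit Inhba was 15.2-fold and 22.9-fold lower, Sfrp1 50.2-fold lower in subcutaneous fat and the Wnt receptor Fzd2 32.1-fold lower in intraabdominal fat. Other genes far lower in adipocytes were Aebp1, a regulator of fibroblast matrix genes (158-fold and 200-fold), Tmem45a (323-fold and 109-fold), Phldb2 (83.2-fold and 130-fold). In subcutaneous fat they included Thbs2 (139-fold), Mmp3 (106-fold), Cyp1b1 (105-fold) and the chemokine Cxcl12 (95.2-fold). In intraabdominal fat they included the protease Prss23 (148-fold), Cck (135-fold), Cnn1 (125-fold) and Igfbp3 (116-fold).

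Endothelial markers were higher in adipocytes than in stromo-vascular cells, 12 of 13 in each depot (12 when adjusted over the list alone, with 1 lower in intraabdominal fat). The medians were 1.92 and 2.29 (adjusted p = 1.12e-05 and 8.31e-06, adjusted p = 0.121 and 0.115 with an estimated correlation). Cdh5 read 5517 ± 1514 against 379 ± 78.8 (13-fold) and 5027 ± 180 against 66.8 ± 31.9 (48.8-fold). Immediate early and dissociation stress genes were higher in 17 of 26 and lower in 6 in subcutaneous fat (18 and 6 when adjusted over the list alone; adjusted p = 0.00086, adjusted p = 0.193 with an estimated correlation). In intraabdominal fat 17 were higher and 3 lower (17 and 3 when adjusted over the list alone; adjusted p = 0.000117, adjusted p = 0.134 with an estimated correlation). They were led by Fosb (43.5-fold and 55.1-fold), Zfp36 (13-fold and 9.30-fold) and in intraabdominal fat Egr2 (5.75-fold). Erythroid markers were higher in 3 of 8 and 5 of 8 genes (2 and 5 when adjusted over the list alone; adjusted p = 0.0368 and 0.039, adjusted p = 0.243 and 0.249 with an estimated correlation). The hemoglobin chain Hba-a1 was 45.4-fold and 51.5-fold and Hbb-b2 22.8-fold and 35.4-fold higher. Red cells had been lysed in the stromo-vascular fraction. Complement and coagulation genes were lower in 12 and higher in 2 of 19 in subcutaneous fat (12 and 2 when adjusted over the list alone; adjusted p = 0.00244, adjusted p = 0.108 with an estimated correlation). In intraabdominal fat 10 were lower and 2 higher (11 and 2 when adjusted over the list alone; adjusted p = 0.0166, adjusted p = 0.145 with an estimated correlation). In subcutaneous fat Serping1, an inhibitor of complement, was 27.3-fold lower, Cd59a, which protects cells from complement, 31.7-fold higher and the actin-severing protein Gsn 7.47-fold higher.

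Among the other lists, the patterning regulators were called in both depots and the rest described here in 1, without a test of every such difference. Hox genes were higher in 10 of 21 cases in subcutaneous adipocytes (10 when adjusted over the list alone; adjusted p = 0.014, adjusted p = 0.141 with an estimated correlation). In intraabdominal fat 5 were higher and 3 lower (5 and 2 when adjusted over the list alone; list adjusted p = 0.672, median -0.06 against a mean of 0.08). Hoxb5 was 3.25-fold and 2.96-fold higher in adipocytes of the respective depots. Other patterning regulators were lower in 16 of 39 in subcutaneous fat with 1 higher (15 and 1 when adjusted over the list alone; adjusted p = 0.0446, adjusted p = 0.383 with an estimated correlation). In intraabdominal fat 21 were lower and 1 higher (21 and 1 when adjusted over the list alone; adjusted p = 0.000764, adjusted p = 0.145 with an estimated correlation). En1 was 4.72-fold and 12-fold lower, and Prrx1, a regulator of limb mesenchyme, 9.76-fold lower in subcutaneous fat. In intraabdominal fat smooth muscle and pericyte markers were lower in 9 and higher in 2 of 12 (the same when adjusted over the list alone; adjusted p = 0.00283, adjusted p = 0.135 with an estimated correlation). The actin-binding Tagln was 66.7-fold and Actg2 10.3-fold lower. Mesothelial markers were lower in 6 of 7 there (6 when adjusted over the list alone; adjusted p = 0.0166, adjusted p = 0.134 with an estimated correlation), Wt1 by 6.00-fold. Cell cycle genes were lower in 16 of 25 (17 when adjusted over the list alone; adjusted p = 0.00138, adjusted p = 0.0287 with an estimated correlation), Rrm1 by 33.9-fold. Glycolysis and hypoxia genes were lower in 12 and higher in 3 of 17 (the same when adjusted over the list alone; adjusted p = 0.00283, adjusted p = 0.145 with an estimated correlation), the glycolytic kinase Pgk1 by 3.64-fold. Cholesterol synthesis genes were higher in 9 and lower in 1 of 13 (10 and 2 when adjusted over the list alone; adjusted p = 0.00618, adjusted p = 0.0538 with an estimated correlation). Macrophage markers were lower in 10 and higher in 4 of 17 there (11 and 4 when adjusted over the list alone; median -1.04, adjusted p = 0.0366, adjusted p = 0.503 with an estimated correlation), the lysozyme Lyz2 by 7.62-fold and the protease Ctss by 8.91-fold. In subcutaneous fat 5 were higher and 5 lower (5 and 6 when adjusted over the list alone; list adjusted p = 0.699), and C1qa and C1qb were 16-fold and 30.7-fold higher in adipocytes. Of single immune genes Cxcl9 was 62.6-fold and 45.7-fold and the antibody chain Ighm 23.3-fold and 88.5-fold higher in adipocytes, with an uncalled Ighm probe set of the other sign in subcutaneous fat. The macrophage growth factor Csf1 was 20.6-fold and 19.6-fold lower.

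Adipocyte arrays had the higher actin 3' to 5' ratio in both of these comparisons. With that ratio as a covariate, chosen after seeing the data, 1058 probe sets were called in subcutaneous and 2173 in intraabdominal fat. Of the calls made without it 4046 of 4594 (88.07%) and 4309 of 4462 (96.57%) kept their sign, and the median standard error rose from 0.241 to 0.796 and 0.547. The spiked bacterial controls also read higher in adipocytes (exact permutation p = 0.0022 over all 12 arrays). In subcutaneous fat the adjusted p then reached 0.076 for Cdh5, 0.0802 for Hba-a1, 0.0912 for Hbb-b2, 0.056 for Ighm, 0.131 for En1 and 0.179 for Prrx1, and in intraabdominal fat 0.0518 for Ctss. The lowest values over alternatives were between 9.17e-10 (Ighm) and 9.16e-07 (En1). The log2 difference (± SE) went from 3.70 ± 0.253 to 2.34 ± 0.793 for Cdh5, 5.51 ± 0.363 to 3.24 ± 1.12 for Hba-a1, 4.51 ± 0.356 to 3.39 ± 1.21 for Hbb-b2 and 4.54 ± 0.338 to 3.78 ± 1.18 for Ighm. It went from -2.24 ± 0.311 to -2.70 ± 1.08 for En1, -3.29 ± 0.414 to -3.28 ± 1.47 for Prrx1 and -3.16 ± 0.304 to -1.72 ± 0.597 for Ctss. Among lists the covariate ended the subcutaneous calls of endothelial (adjusted p = 0.054), erythroid (0.183) and Hox genes (0.117) and the intraabdominal calls of complement (0.0527), erythroid (0.1) and macrophage genes (0.705). The mean of all probe sets of a gene also ended the macrophage call (0.135). The call of the other patterning regulators in subcutaneous fat was lost without subcutaneous adipocyte array 3 (adjusted p = 0.0673) or stromo-vascular array 3 (0.0533). In intraabdominal fat the erythroid call was lost without adipocyte array 3 (0.08) or stromo-vascular array 3 (0.0507), and the macrophage call without adipocyte array 2 (0.072) or 3 (0.0644).

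**Figure D4:**
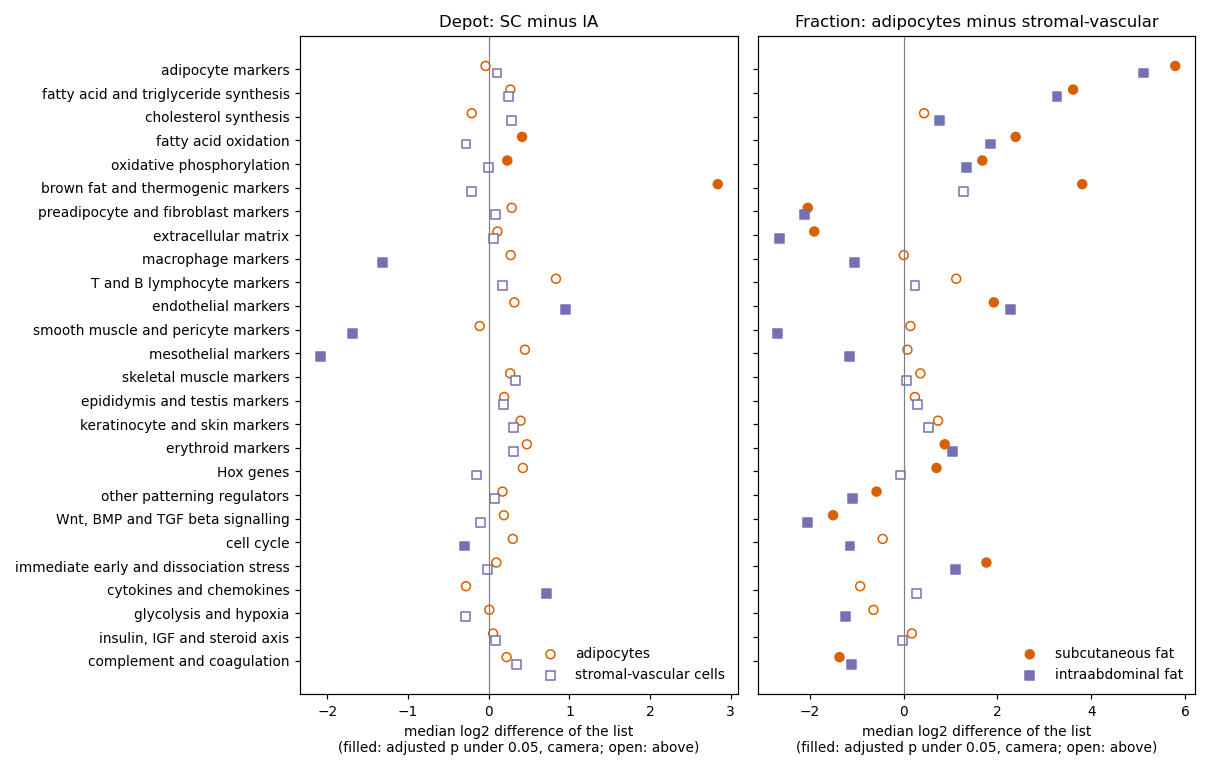
Median log2 difference of 26 gene lists in the depot comparisons (subcutaneous minus intraabdominal) and the fraction comparisons (adipocytes minus stromo-vascular cells), 3 arrays per group; a filled point marks an adjusted p under 0.05. Adipocyte markers had medians of 5.79 and 5.12 in the fraction comparisons and -0.04 in the adipocyte depot comparison, where brown fat markers reached 2.84.

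The last comparison asked which depot differences themselves differed between adipocytes and stromo-vascular cells, as the difference in adipocytes minus that in stromo-vascular cells. The smooth muscle genes Cnn1 (log2 difference 7.14, adjusted p = 3.43e-06) and Myh11 (5.60, adjusted p = 0.000341) were lower in subcutaneous than in intraabdominal stromo-vascular cells, whereas in adipocytes neither was called (adjusted p = 0.199 and 0.753). Mup3 (5.20, adjusted p = 7.22e-06), Cidea (5.01, adjusted p = 4.4e-05) and Bnc1 (4.71, adjusted p = 0.000216) also had a depot difference further toward subcutaneous cells in adipocytes. In the other direction stood Agt (-5.50, adjusted p = 4.23e-09), Serpinb2 (-4.49, adjusted p = 3.92e-06), Serpina3n (-4.18, adjusted p = 1.02e-06), Ccl8 (-3.88, adjusted p = 3.95e-05) and Myl1 (-3.60, adjusted p = 5.61e-05). Of 8695 probe sets 733 (8.43%) passed, 339 positive and 394 negative. With each array centred on its median 33.0% of the calls were positive against 46.2% as deposited, and with the actin covariate 403 passed. Of 26 lists 11 were called, 9 positive and 2 negative (named below). With an estimated correlation 4 were called (adjusted p = 0.0354 each).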

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

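The tests of technical and biological explanations for the 3 patterns at the end of this part were chosen only after the results were seen, and so were the actin and GAPDH covariates, while the interaction test and the counts over other splits of the samples were planned. Every value in the next 4 paragraphs differed between the fractions by the planned interaction test (limma, adjusted p from 4.23e-09 to 0.0476 for single genes), given as the log2 depot difference in adipocytes minus that in stromo-vascular cells, over 3 arrays per group. In all 733 probe sets passed it, and so did 75 of the 124 genes named, 44 positive and 31 negative.

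Brown fat markers shifted by a median of 2.46 (adjusted p = 1.55e-06, adjusted p = 0.0513 with an estimated correlation), fatty acid oxidation by 0.58 (adjusted p = 0.000107, 0.0354 with an estimated correlation) and oxidative phosphorylation by 0.37 (adjusted p = 0.00164, adjusted p = 0.341 with an estimated correlation). Smooth muscle and pericyte markers shifted by 1.40 (adjusted p = 5.09e-09, 0.0354 with an estimated correlation), mesothelial markers by 2.41 (adjusted p = 2.21e-05, 0.0354 with an estimated correlation). Macrophage markers shifted by 1.66 (adjusted p = 4.7e-08, adjusted p = 0.138 with an estimated correlation) and cell cycle genes by 0.65 (adjusted p = 0.000371, 0.0354 with an estimated correlation). Hox genes shifted by 0.52 (adjusted p = 0.00147, adjusted p = 0.0726 with an estimated correlation) and other patterning regulators by 0.42 (adjusted p = 0.0107, adjusted p = 0.341 with an estimated correlation). The latter call was lost without subcutaneous adipocyte array 2 (adjusted p = 0.0747). Neither list is independent of published work on these depots. Cytokines and chemokines shifted by -1.23 (adjusted p = 4.7e-08, adjusted p = 0.0607 with an estimated correlation) and cholesterol synthesis by -0.46 (adjusted p = 0.0107, adjusted p = 0.0607 with an estimated correlation).

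Positive genes of muscle, matrix and growth factor binding were Cnn1 (7.14), Myh11 (5.60), Actg2 (3.55), Tagln (2.22), Igfbp2 (3.88), Igfbp3 (3.28), Timp3 (3.49), Col1a1 (2.11), Col1a2 (1.53), Postn (0.98) and Prss23 (1.75). Those of fat metabolism and mitochondria were Cidea (5.01), Ucp1 (2.62), Cox7a1 (2.78), Cox8b (2.30), Elovl6 (1.88), Hadhb (1.11) and Cd36 (1.60). Patterning and mesothelial genes were Bnc1 (4.71), Tcf21 (3.95), Wt1 (2.58), Upk3b (2.41), Scx (2.39), Nr2f2 (2.17), Gata2 (1.97), Hoxa5 (1.67), Hoxa7 (1.52), Gata6 (1.21), Hoxc9 (1.18), Gpc4 (1.16) and Hoxc8 (0.88). Macrophage and complement genes were C1qb (3.28), C1qa (3.21), Cd59a (2.43), Mpeg1 (1.76) and Lyz2 (1.49), and the others were Mup3 (5.20), Mup5 (4.33), Cck (4.66), Vamp5 (4.21), Aldh1a3 (4.15), Rrm1 (1.74), Clu (1.40) and Socs3 (1.07).

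Negative genes of fat cells and lipid handling were Agt (-5.50), Plin4 (-2.39), Rbp4 (-2.15), Ghr (-1.05) and Scd1 (-0.89). Secreted immune proteins were Serpinb2 (-4.49), Serpina3n (-4.18), Ccl8 (-3.88), Lcn2 (-3.11), Ccl11 (-2.97), C2 (-2.47), Saa3 (-2.21), Cxcl14 (-2.01), Ighm (-1.92) and Cxcl12 (-1.23). The others were Myl1 (-3.60), Tgfb1 (-3.10), Fosl1 (-2.73), Acta1 (-2.61), Dpt (-2.61), Rhbdl3 (-2.45), Ramp2 (-2.40), Irx3 (-2.17), Cyp1b1 (-2.17), Slc2a1 (-2.08), Ogn (-2.08), Col6a1 (-1.95), Cdh5 (-1.90), Itm2a (-1.80), Tmem45a (-1.57) and Nr4a1 (-1.46).

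Leaving out 1 array ended some of these gene calls, while the differences kept their sign (1.23 to 1.67 for Hoxa7). That of Hoxa7 held only without subcutaneous adipocyte array 3 or subcutaneous stromo-vascular array 2 (up to 0.114, without subcutaneous stromo-vascular array 3), and that of Prss23 only without subcutaneous adipocyte array 1 or intraabdominal adipocyte array 3 (up to 0.105, without subcutaneous stromo-vascular array 3). That of Slc2a1 held only without array 3 of either adipocyte group (up to 0.099, without intraabdominal adipocyte array 1). Hoxc8 was lost without any array (up to 0.0941, without intraabdominal adipocyte array 2) except subcutaneous adipocyte arrays 1 and 2 and intraabdominal adipocyte array 3. Scx was lost without any array (up to 0.11, without subcutaneous stromo-vascular array 3) except subcutaneous adipocyte array 1, intraabdominal adipocyte array 3, subcutaneous stromo-vascular array 2 and intraabdominal stromo-vascular array 3. Rrm1 was lost without intraabdominal adipocyte array 1 (0.0516), subcutaneous stromo-vascular array 1 (0.0509) or 2 (0.0762) or intraabdominal stromo-vascular array 2 (0.0732) or 3 (0.0643), and Ighm without intraabdominal adipocyte array 1 (0.0538) or 2 (0.056). Over all alternatives the adjusted p ran from 0.0229 to 0.226 for Hoxa7, 0.00252 to 0.13 for Prss23, 2.11e-05 to 0.3 for Slc2a1, 0.0139 to 0.12 for Hoxc8, 0.00432 to 0.241 for Scx, 0.00243 to 0.14 for Rrm1 and 0.000523 to 0.0734 for Ighm. The actin covariate ended the calls of Ccl11 (adjusted p = 0.0726), Gata6 (0.103), Hoxa5 (0.0673), Hoxc9 (0.11), Nr2f2 (0.142), Postn (0.0623), Tmem45a (0.0653), Ucp1 (0.0838) and Wt1 (0.0828), and of the lists of cholesterol synthesis (0.0853) and other patterning regulators (0.0839; 0.0732 without a filter), and median centring that of Socs3 (0.0525). The covariate raised the median standard error from 0.341 to 0.423, and the differences of these genes kept their sign. They were 2.22 ± 0.662 (SE) for Ucp1 against 2.62 ± 0.525 without it, and 1.41 ± 0.492 for Nr2f2 against 2.17 ± 0.448.

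Other splits of the arrays were fitted to see how many calls a wrong assignment gives. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most calls: 707 against at most 4 for adipocyte depots and 1125 against 1 for stromo-vascular depots. For the fractions it gave 4594 in subcutaneous and 4462 in intraabdominal fat, against 0. A wrong split puts the real difference into the spread, so these counts show no chance level. Of gene lists, 4 of 10 splits called as many as the real 3 in the adipocyte depot contrast (highest other 5), 2 as many as the real 6 in the stromo-vascular depot contrast (highest other 8). In the fraction contrasts only the real split called as many, 14 (highest other 12) and 18 (highest other 15). For the interaction 100 assignments of the depot within each fraction were fitted. As many as 733 calls came from 2 of them, the real one and another with 1306. That other assignment exchanged the depots within the stromo-vascular arrays only, so it tests the depot difference averaged over the fractions, a structure of these samples. The highest of the other 98 gave 511. The 162 shared depot calls were reached by 1 of 100 assignments, the real one (highest other 66). An assignment that mixes the depots leaves few depot calls that could be shared, so this rank does not show whether the sharing exceeds chance. The 11 lists of the interaction were reached by 2 of 100, the real one and a wrong one with 11 too. That one was not the exchange of the stromo-vascular depots, which gave 6, so a wrong assignment can call as many lists as the real one.

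A first pattern was the higher level of brown fat genes in subcutaneous adipocytes. Broken RNA cannot be told apart from the depot, since the actin 3' to 5' ratio separated the adipocyte depots. As a covariate it gave a list median of 2.99, against 2.84 without (adjusted p = 2.44e-08 and 2.1e-07). Without it an estimated correlation gave adjusted p = 0.145. With the GAPDH ratio the median was 3.01 (median standard error 0.555, adjusted p = 1.71e-08). With the actin ratio the median standard error grew from 0.368 to 0.610 and 3 instead of 5 of its 6 genes were called. Skeletal muscle in the flank tissue was argued against, since the muscle list had a median of 0.27 and Acta1 was lower in subcutaneous adipocytes. Brown or thermogenic adipocytes among the fat cells may account for it, with Ucp1 at a log2 difference of 2.93, but this cannot be told apart from a higher level of these genes in every fat cell, because single cells were not measured, and the depots' anatomical difference also stays open.

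A second pattern was the higher level of smooth muscle and mesothelial genes in intraabdominal stromo-vascular cells. A lower share of fibroblast-like cells there would raise the markers of every other cell type alike, yet endothelial markers had a median of 0.95 ± 0.294 (SE over genes; list adjusted p = 0.0178, adjusted p = 0.389 with an estimated correlation, and 0.157 with the GAPDH covariate at a median of 0.90 and 3 instead of 7 genes called), higher in subcutaneous cells, against -1.69 ± 0.743 for smooth muscle, although macrophage markers moved with the latter (-1.31 ± 0.318). The actin ratio barely moved this contrast and decided nothing. With the GAPDH ratio as a covariate, which moved 1125 calls to 764, the smooth muscle median was -1.92 (median standard error 0.338, adjusted p = 2.09e-14). The mesothelial one was -1.88 (0.430, adjusted p = 2.18e-06). That ratio separated the depots, so broken RNA stays open. More mesothelial or contractile cells in the intraabdominal tissue are a candidate explanation, with a mesothelial median of -2.09. This cannot be told apart from higher levels of the same genes within stromal cells of that depot after plating, since the cells were not sorted.

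The last pattern was the higher level of endothelial genes in adipocytes than in stromo-vascular cells, the fraction that holds vessels. Scaling moves all probe sets of an array by 1 factor, so it cannot set the list (median 2.29 in intraabdominal fat) apart from all probe sets (-0.11). Whether the common level of the 2 fractions was right cannot be decided from these medians, since the arrays had been scaled to 1 level beforehand. The spiked controls read 15365 ± 7238 in intraabdominal adipocytes against 5868 ± 941 in intraabdominal stromo-vascular cells. RNA integrity cannot be told apart from the fraction: with the actin covariate the list median in subcutaneous fat went from 1.92 to 0.96, its median standard error from 0.266 to 0.887 and its called genes from 12 to 1 (list adjusted p = 0.054), and the ratio separates the fractions. The list stayed called in subcutaneous fat with the GAPDH ratio (median 1.47, median standard error 0.915, adjusted p = 0.0278), but 0 instead of 12 of its genes were called. In intraabdominal fat it stayed called with the actin (1.26, 0.610, adjusted p = 0.00116, 6 genes) and the GAPDH ratio (1.94, 0.817, adjusted p = 0.00372, 4 genes). Without a covariate but with an estimated correlation the list was called in neither depot (adjusted p = 0.121 and 0.115). Vessel cells carried along with floating adipocytes may account for the 2.29, which cannot be told apart from loss of endothelial cells or of their transcripts during plating.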

How the results depend on the processing

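The fits with the actin or the GAPDH 3' to 5' ratio as a covariate were chosen after seeing the data, and the other alternatives were planned. None of the called gene and list results given here turned its direction. Of 270 gene results 260 were called, 17 lost the call without some array and 45 under another alternative except the 2-fold minimum, 40 of them under the actin covariate. Of 130 list results 52 were called, none with a reversed sign (27 list and 6 gene results that were not called changed sign somewhere). Against 707, the adipocyte depot contrast called 297 probe sets with only the 6 arrays compared, 283 with the 2-fold minimum and 97 with the actin covariate. Against 1125, the stromo-vascular one called 1952 with array quality weights, 1690 with the 6 arrays and 544 with the 2-fold minimum. The 2-fold minimum gave 2888 in subcutaneous and 2869 in intraabdominal fat for the fractions, and the actin covariate 1058 and 2173, and 403 for the interaction. Shared depot calls numbered 106 without the intensity trend, 91 with the 6 arrays, 37 with the 2-fold minimum and 39 with the actin covariate, against 162. The GAPDH ratio, fitted only for counts and tests of explanations, gave 148 calls in adipocytes, 764 in stromo-vascular cells, 783 and 1097 for the fractions, 652 for the interaction, 51 shared calls and 5 lists in adipocytes. The cause of these moves was not tested, except that the 2-fold minimum removes calls by construction and that the actin covariate raised the median standard error from 0.241 to 0.381 in adipocytes. With it 705 of 707 calls kept their sign in adipocytes (80 called in both fits), all 1125 in stromo-vascular cells and all 733 of the interaction. For the fractions 983 and 2009 were called in both fits. Lists called in the adipocyte depot contrast, 3 with camera, were 1 with median centring, 5 without a filter, 5 with the actin covariate, 5 with the mean of all probe sets and 0 with camera's estimated correlation, where 4 had an unadjusted p under 0.05 and fry called 4. The estimated correlation gave 2 lists for stromo-vascular depots, 5 and 6 for the fractions of subcutaneous and intraabdominal fat and 4 for the interaction, while fry, which does not compare a list with other genes, gave 14 for stromo-vascular depots and 22 for the fractions of subcutaneous fat.

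Leaving out 1 array gave 365 calls (without intraabdominal adipocyte array 2) to 949 (without array 3) in the adipocyte depot contrast. It gave 765 to 1273 in the stromo-vascular one, 3957 to 4660 and 4001 to 4647 for the fractions, 538 to 820 for the interaction, and 96 (without intraabdominal adipocyte array 1) to 196 shared depot calls. Lists called ranged from 1 (without subcutaneous adipocyte array 3) to 4, 5 to 8, 13 to 14, 16 to 19 and 10 to 12 in the order of the contrasts. With replicate number as a block the calls were 595, 1054, 4506, 4406 and 645, and 135 were shared. The block ended the calls of Gata2 in adipocytes (adjusted p = 0.0502) and Scx in the interaction (0.0599) and added that of the fatty acid oxidation list in the stromo-vascular depot contrast. Residuals of arrays of 1 number in different groups correlated between -0.086 and 0.111 over 18 pairs, with 3 of 12 arrays closest to their own number, so the numbers were not taken to pair the samples. The filter of 60% gave a value for 193 of the gene results, and the fit of 6 arrays none for the interaction. Folds of dim genes are pulled toward 1 by the pseudocount, and dim groups near it (Tcf21 at 50.2 in subcutaneous stromo-vascular cells) give folds that understate the difference.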

Other observations

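No test in this part was chosen only after its result was seen except the actin covariate. Genes of other functions also separated the groups. Of complement and coagulation genes 2 of 19 were higher and 3 lower in subcutaneous adipocytes (5 and 4 when adjusted over the list alone; list adjusted p = 0.673). In turn 5 were higher and 3 lower in subcutaneous stromo-vascular cells (7 and 3 when adjusted over the list alone; list adjusted p = 0.298). There complement factor C2 read 13136 ± 1682 against 2334 ± 308 (5.55-fold, adjusted p = 1.17e-07, all 3 arrays above all 3). Tissue factor F3, which starts coagulation, was 17.5-fold and 12.2-fold higher in stromo-vascular cells than in adipocytes of subcutaneous and intraabdominal fat (adjusted p = 6.47e-12 and 2.43e-11), reading 48245 ± 2369 and 43154 ± 2998. P4ha1, which hydroxylates collagen and responds to low oxygen, was 12.8-fold and 17.0-fold higher in the same cells. Of glycolysis and hypoxia genes 5 of 17 were higher and 9 lower in subcutaneous adipocytes than in stromo-vascular cells (the same when adjusted over the list alone; list adjusted p = 0.0725). In the depot contrasts the list's adjusted p was 0.501 in adipocytes (median 0.01 against a mean of -0.12) and 0.0637 in stromo-vascular cells. The growth hormone receptor Ghr was 8.86-fold and 18.4-fold higher in adipocytes than in stromo-vascular cells (adjusted p = 6.98e-11 and 2.87e-12), in a list of insulin, IGF and steroid genes that was not called in either depot (adjusted p = 0.348 and 0.422) or between adipocyte depots (0.615).

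Markers of tissues next to the depots were mostly not called. Of 8 epididymis and testis markers none was called between adipocyte depots (list adjusted p = 0.844). In turn 1 was higher and 1 lower in subcutaneous stromo-vascular cells (list adjusted p = 0.914, median 0.19 and test direction down). The lower one was Clu, clusterin, a secreted chaperone of many tissues, at 895 ± 46.7 against 3024 ± 188 (3.27-fold, adjusted p = 2.86e-06). In the fraction contrasts that list's adjusted p was 0.348 and 0.516. Keratinocyte and skin markers gave no call among 6 in either depot contrast (list adjusted p = 0.295 and 0.62). In subcutaneous fat 3 were higher in adipocytes than in stromo-vascular cells (list adjusted p = 0.239; 0.33 in intraabdominal fat). Krt10, a skin keratin, read 347 ± 157 against 88.9 ± 19.1 (2.82-fold, adjusted p = 0.00523; 0.000734 to 0.191 over alternatives, the highest with the actin covariate). Skeletal muscle markers had adjusted p = 0.0795 in the stromo-vascular depot contrast (2 higher and 1 lower of 12) and 0.434 and 0.248 between the fractions. Myl1 was 45.9-fold higher in intraabdominal adipocytes than in stromo-vascular cells (5226 ± 159 against 87.7 ± 75.7). Of 8 T and B lymphocyte markers 1 was lower in subcutaneous adipocytes (3 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.194), and none was called in stromo-vascular cells (list adjusted p = 0.914). In the fraction contrasts 4 and 2 were higher in adipocytes than in stromo-vascular cells, with 1 lower in intraabdominal fat (list adjusted p = 0.0739 and 0.422). The lower one in subcutaneous adipocytes was Ighm, the heavy chain of IgM, at 12925 ± 1421 against 30561 ± 5127 (2.35-fold, adjusted p = 0.0386). That call was lost without any of the 3 subcutaneous adipocyte arrays, intraabdominal adipocyte array 1 or 2, any of the 3 subcutaneous stromo-vascular arrays or intraabdominal stromo-vascular array 3 (up to 0.131, without intraabdominal adipocyte array 2). Its adjusted p ran from 0.0028 to 0.251 over all alternatives. Cholesterol synthesis had 1 of 13 genes lower in subcutaneous adipocytes (list adjusted p = 0.103), 3 higher in subcutaneous stromo-vascular cells (0.171), and 5 higher and 2 lower in subcutaneous adipocytes than in stromo-vascular cells (0.132). Erythroid markers were not called between depots (adjusted p = 0.295 and 0.292).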
